A study of Mus musculus with 44 samples.

How the data were processed

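The series holds 44 single Tomato-positive cells from hindlimb muscle of adult Prrx1-CreERT;Tomato mice, in 1 group. In these mice tamoxifen activates a Cre recombinase made under Prrx1 control, which switches on a red fluorescent reporter. Per the labels, each mouse received 2 mg of tamoxifen once a day for 3 days. Muscle was digested with collagenase and dispase, Tomato-positive cells were sorted, and single cells were then picked under a fluorescence microscope and made into Nextera XT libraries. The labels name no animals, so the 44 cells count as 1 sample, no p-value was computed, and comparisons between cells describe these cells only.

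The authors deposited 1 table of log2 values for 12745 rows and 44 cells, whose name gives FPKM (fragments per kilobase of transcript, scaled to library size). Per the submitters' processing notes, GRCm38, TopHat2 and Cufflinks were used, with no versions given. The logarithm was read from the values: the highest is 14.9, and 2 to the power of the value, minus 1, sums to between 579623 and 579912 per cell. With base e the sum would be at least 15770980, so base 2 was used. The base is an inference and is not given in the sources used here. The design had assumed FPKM, so the planned threshold of FPKM 1 was applied as a log2 value of 1. The sorted values of the 44 cells differed by at most 0.0876 over the 4000 highest ranks, and each cell had 4022 rows at a log2 value of 1 or more. The values had therefore been forced to a shared distribution before deposit, a step not given in the sources used here. The number of genes detected per cell at FPKM 1 is fixed by this step, sequencing depth is unknown, and levels are ranks within a cell more than amounts of RNA. The lowest value was 0 except in 2 cells.

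Gene IDs matched the reference names in 12711 rows. A total of 18 symbols written as dates were restored from the gene ID, and 12 gene IDs stood on more than 1 row. Where a symbol had several rows, the row with the highest mean was kept, which left 12707 symbols. Coordinates come from the GENCODE annotation of GRCm38. The table holds no row for the reporter, for mitochondrially encoded genes or for 63 of the 392 list genes, which are not analysed here.

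At the outset, 32 gene lists, the thresholds, the clustering and the rule for named genes were fixed. A cell was kept with at least 1000 genes at FPKM 1 or more, and all 44 were kept. For each list gene the share of cells at the threshold was computed with an exact Clopper-Pearson 95% interval, which covers counting error only. Cells with at least 3 measured markers of a list were counted. Co-detection with Prrx1 was described by observed and expected numbers of cells and an odds ratio with 0.5 added to each count. Cells were clustered on the 1000 most variable genes outside the lists and present in at least 4 cells, with 10 principal components, Ward linkage and the number of clusters from 2 to 6 with the largest mean silhouette. Variable genes were ranked by variance above a running median over 201 genes of like mean. The text names, per list, the 4 measured members in the largest share of cells and up to 2 in the smallest, 13 genes fixed in advance of which Pax7, Myod1 and Scx are not analysed here, the 10 most abundant and 10 most variable genes, and the leading genes of clusters. Leading genes of the clusters that followed linked libraries are left out, except genes that another part of the rule names or a fixed list holds. Of the genes that this rule names, 1 other is left out of the results. Doublets were not called, since the cells had been picked by hand, and whether any remained was not tested.

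After the data were examined, a threshold of a log2 value of 5 (FPKM 31) was added, because low values proved to be shared between particular cells. This value lies beside a shallow low point of the value spectrum, with 173 rows per cell between 4.5 and 5 and 183 between 6 and 6.5. Linked cells were found from rank correlations over every other row, with a threshold of 0.540 set by Otsu's method, and carry-over was measured on the remaining rows. A second added threshold asked for FPKM 1 or more and over 5 times the signal expected from linked cells. An added clustering set values under 5 to 5. Alternatives fixed before the data were examined were other thresholds, scaling each cell to a sum of 1000000 (TPM), other marker counts and other clustering settings.

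The link and clustering steps were tested on simulated data with 44 cells and 12707 genes, of which 200 differed between groups of cells. With a simulated carry-over of 0.3%, 95.3% of pairs were linked or left unlinked correctly and the estimated rate was 0.3%. Without carry-over the link step still linked pairs, and only 58.8% were placed correctly, so links alone are no evidence of carry-over. In that case the held-out measure gave 0.302% of linked and 0.272% of unlinked cells above the lowest value. With carry-over it gave 64.7% and 6.21%. The planned clustering placed 100% of the simulated cells correctly with carry-over, and the added one 97.7%. The simulated groups differed strongly, were spread evenly over the simulated index layout and were not forced to a shared distribution. These shares therefore do not show how either clustering behaves in the real cells, where the planned one followed linked libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, networkx 3.6.1 and matplotlib 3.10.9 were used.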

Results

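Transcriptomes of 44 single cells labelled through Prrx1-CreERT were measured in adult mouse hindlimb muscle. Prrx1 is a homeobox transcription factor of limb mesenchyme, and the design asks which cells carry the label after 3 daily injections of tamoxifen. All cells belong to 1 group with no named animals, so values are given over cells with no p-value. Shares are given at the planned threshold of FPKM 1 and at an added one of FPKM 31, a log2 value of 5, chosen after the data were seen. Low values were shared between linked libraries: genes strong in 1 cell stood above the lowest value in 80.4% of linked and 19.7% of unlinked cells of the same set. At FPKM 1 or more the shares were 35.99% and 6.14%, and at FPKM 10 or more 2.06% and 1.93%. These genes were picked to reach a log2 value of 7 in 1 cell and to stay under 5 in all others. Genes strong in several linked cells were thus left out. The shares therefore cannot show whether values at the higher threshold are free of carried signal. Each cell had 4022 rows at FPKM 1 or more and 1540 at FPKM 31 or more, numbers set by the deposited normalization.

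Prrx1 (ENSMUSG00000026586, chromosome 1, 163245119 to 163313710, minus strand, GRCm38) was present in 41 of 44 cells at FPKM 1 (93.2%, exact 95% interval 81.3 to 98.6). At the higher threshold it was present in 23 cells (52.3%, 36.7 to 67.5). Its median log2 value was 5.11, with quartiles of 2.14 and 6.28. The surface proteins Ly6a (Sca-1) and Cd34, used to sort muscle mesenchymal progenitors, had medians of 11.82 and 9.07. At the higher threshold Ly6a was present in 44 cells and Cd34 in 39. Over 5 times the signal expected from linked cells, each was present in 38. The remaining cells with Ly6a at the higher threshold cannot be told apart from carried signal. Pdgfra, the receptor that marks fibro-adipogenic progenitors, had a median of 6.47 and was present in 44 cells at FPKM 1 and 31 at the higher threshold. The mural and stromal receptor Pdgfrb was present in 36 and 18 cells.

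**Figure D1:**
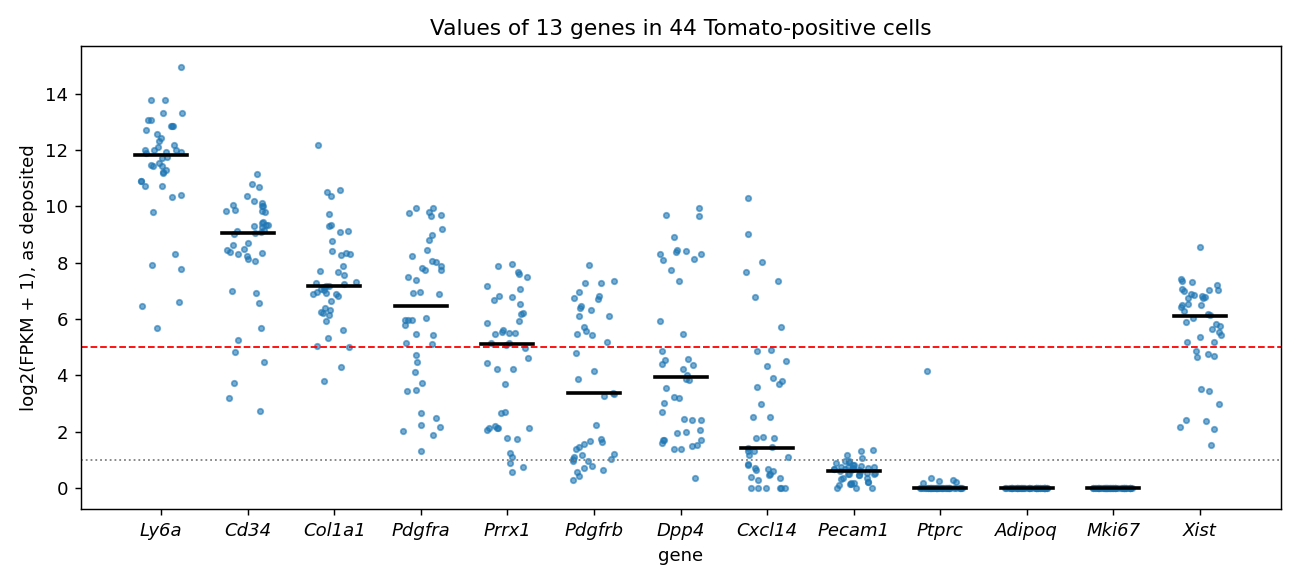
Log2(FPKM + 1) of 13 genes in each of the 44 cells (points, spread sideways at random), with the median as a black bar, FPKM 1 as a dotted line and the added threshold of 5 as a dashed line. Ly6a lies above 5 in 44 cells, Prrx1 in 23, and Pecam1, Ptprc, Adipoq and Mki67 in 0.

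All 12 measured genes of the fibro-adipogenic progenitor or fibroblast list were present in at least 22 cells at both thresholds. Per cell, a median of 10 of the 12 reached the higher threshold, with a range of 3 to 12. Over 5 times the signal expected from linked cells the median was also 10, with a range of 2 to 12. At least 3 were then held by 42 cells. Cells 8 and 36 held 2 each, cell 40 held 3 and cells 17 and 25 held 5 each. Mfap5, a microfibril protein, was present in 40 cells at the higher threshold, as was Col3a1, and the least frequent member at FPKM 1, Clec3b, in 34. Of 16 collagens, 9 were present in at least 22 cells at the higher threshold and 12 at FPKM 1. The fibrillar chains Col1a2, Col1a1 and Col3a1 were present in 44, 42 and 40 cells and Col6a1 in 38, against 7 for Col5a3 and 4 for Col12a1. Among 23 other matrix genes 15 passed the same mark. Sparc and Serpinf1 were present in 44 cells each, Fbln2 in 40 and Ogn in 37, while Timp1 was present in 4 and Mmp3 in 1.

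Of 21 limb mesenchyme transcription factors, 9 were present in at least 22 cells at FPKM 1 and 5 at the higher threshold. Tcf7l2 was present in 36 cells at the higher threshold, Tcf4 in 31, Osr1 in 27 and Meox2 in 21. Twist2 was present in 6 cells at FPKM 1 and 1 at the higher threshold, and Twist1 in 2 and 0. Among 16 mesenchymal stem or stromal genes, Cxcl12 was present in 27 cells at the higher threshold and Itgb1 in 13. Alcam was present in 1 cell and Nt5e (CD73) in 0.

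Co-detection with Prrx1 was not informative at FPKM 1, where Prrx1 was present in 41 of 44 cells and all 10 pairs lay within 0.864 cells of the number expected from the shares. At the higher threshold 17 cells held both Prrx1 and Pdgfra with 16.2 expected, an odds ratio of 1.39. The pair with Pdgfrb was found in 12 cells with 9.41 expected, and the pair with Dpp4 in 9 with 7.84 expected. Prrx1 and Cxcl14 were found together in 1 cell with 3.66 expected at the higher threshold. Over 5 times the signal expected from linked cells, each of these 4 pairs lay on the other side of the expected number. Prrx1 and Pdgfra were then found together in 23 cells with 24 expected, an odds ratio of 0.589. The pair with Pdgfrb was found in 17 with 17.5 expected, that with Dpp4 in 15 with 16 expected and that with Cxcl14 in 12 with 10.9 expected.

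Apart from Tek, each measured marker of endothelial, blood, glial and muscle stem cells was present in at most 2 cells at the higher threshold. No cell held 3 or more markers of the endothelial, satellite cell, glial, macrophage, neutrophil or lymphocyte lists at either threshold, which allows a share of up to 8.04% each. Pecam1 was present in 4 cells at FPKM 1 and 0 at the higher threshold, with a maximum log2 value of 1.34. Ptprc, the pan-leukocyte gene, was present in 1 and 0. Of the macrophage list Cd68 was present in 9 cells at FPKM 1 and 1 at the higher threshold, Cd14 in 3 and 0, and Itgam, Tyrobp and Fcer1g in 0. S100a9 was present in 4 cells at FPKM 1, the remaining neutrophil genes Cxcr2, S100a8 and Retnlg in 0, and the 6 measured lymphocyte genes in 0. The erythroid genes are not analysed here. Tek was the exception in the endothelial list, in 31 and 14 cells, and it also stands in the Dpp4-type fibroblast list. The satellite cell list rests on 4 measured genes, of which Msc was present in 12 cells at FPKM 1 (27.3%, 14.96 to 42.8) and 2 at the higher threshold, Chodl in 7 and 1, Megf10 in 2 and 1 and Chrna1 in 0. The glial list also rests on 4, with Ncmap in 8 cells at FPKM 1, S100b in 3 and Ngfr in 1, each in 1 cell at the higher threshold, and Mbp in 0. Of the adipocyte list, Adipoq, Cidec and Cfd were present in 0 cells at FPKM 1 and Plin4 in 3.

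Myofibre and mural markers were found in some cells. At the higher threshold 7 cells held at least 3 of 13 myofibre genes (15.9%, 6.64 to 30.1), and cell 31 held 12. These were cells 5, 6, 7, 31, 32, 41 and 44, and each also held 10 to 12 of the 12 fibroblast genes. The count is therefore of fibroblast-like cells with myofibre RNA, the source of which was not tested. Tnnt3 and Mylpf were present in 12 cells each, Tnnc2 in 8 and Mb in 5, against 1 for Pvalb and 0 for Actn3. The pericyte or smooth muscle list also gave 7 cells with at least 3 of 10 markers. Cell 36 held 10 and cell 30 held 8, while no other cell held more than 4. Acta2 was present in 16 cells, Rgs5 in 9, Tagln in 5 and Mcam and Kcnj8 in 2 each. Cells with at least 3 markers of any of these other lineages numbered 41 at FPKM 1 and 13 at the higher threshold, so the planned count moved by over 1.5 times.

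**Figure D2:**
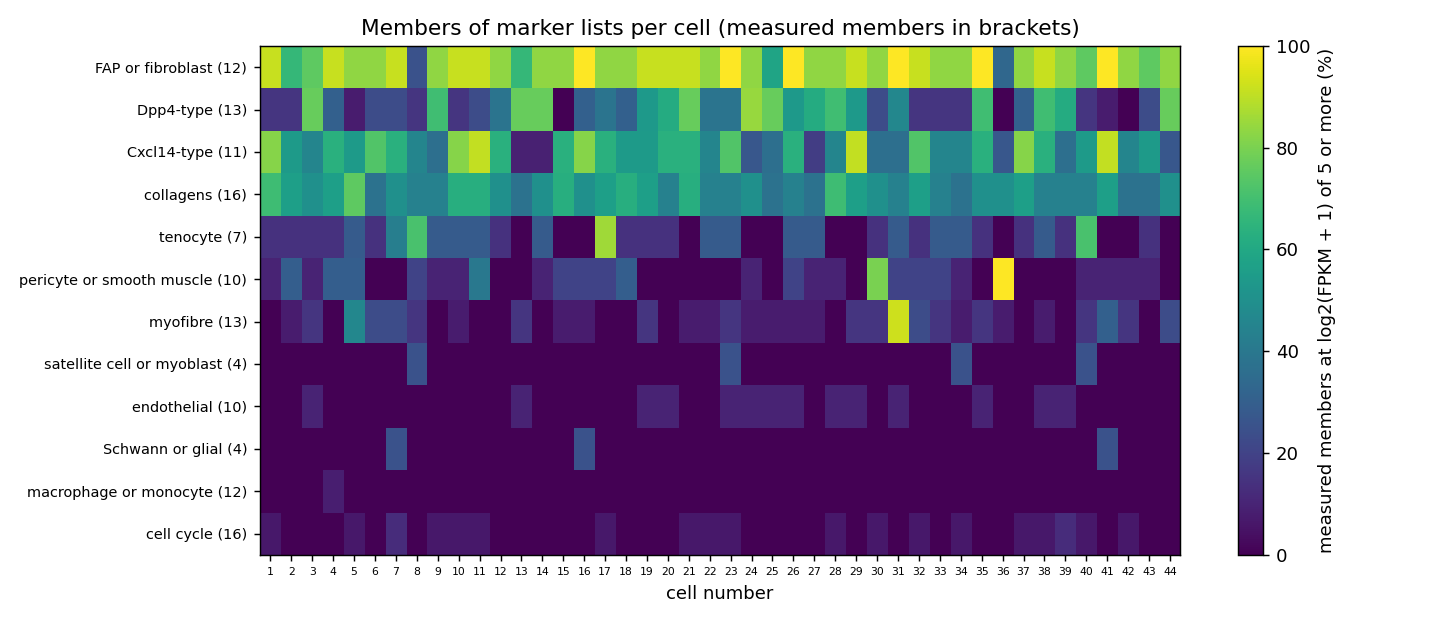
Percent of the measured members of 12 marker lists at a log2 value of 5 or more (colour) in each of the 44 cells (columns), with the number of measured members in brackets. Fibroblast genes fill most columns, cells 30 and 36 stand out in the pericyte or smooth muscle row, cells 8, 17 and 40 in the tenocyte row and cell 31 in the myofibre row.

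Cells differed in fibroblast subset genes. Of 13 Dpp4-type genes, Pcolce2 was present in 33 cells at the higher threshold, Fbn1 in 29, Anxa3 in 28 and Pi16 in 25, against 3 for Opcml and 0 for Wnt2. Of 11 Cxcl14-type genes, Apod was present in 39, Ltbp4 in 37, Lpl in 35 and Lum in 32, against 7 for Cxcl14 and 6 for Col15a1. Of 7 measured tenocyte genes, Fmod was present in 23 cells, Thbs4 in 14, Chad in 8 and Comp in 7, and Kera in 2 and Mkx in 1.

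The planned clustering gave 6 clusters with a mean silhouette of 0.210. They followed 6 blocks of cells with mutually linked libraries (adjusted Rand index 0.815), and they are left unnamed. With values under 5 set to 5, a clustering chosen after the data were seen, 4 clusters of 25, 13, 3 and 3 cells were found with a mean silhouette of 0.162. List genes took no part in either clustering. The cluster of 13 cells held on average 9.08 ± 1.26 Dpp4-type genes per cell at the higher threshold (SD over cells), against 3.52 ± 2.52 in the other 31. It held 4.15 ± 2.15 Cxcl14-type genes against 6.77 ± 1.89. Immediate early and heat shock genes, which rise during tissue digestion, were also fewer in it, with 5.69 ± 2.53 of 17 against 10.2 ± 2.80. Fibro-adipogenic progenitor genes were as many in it, with 10.1 ± 1.38 against 9.97 ± 1.98. Both this cluster and that of 25 cells were thus fibroblast-like. Pi16, Efemp1, Anxa3 and Scara5 led the cluster of 13, and Inmt, Apod, Penk and Apoe that of 25. Membership was not fixed: over 10 settings the cluster with the most Dpp4-type genes held 10 to 15 cells, of which 9 were shared by all settings.

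Cells 8, 17 and 40 formed a tenocyte-like cluster, led by Fmod, Thbs4, Angptl7 and Comp, with 5.33 ± 0.577 of 7 tenocyte genes per cell against 1.07 ± 0.848 in the others. At the higher threshold cell 8 held 3 of the 12 fibro-adipogenic progenitor or fibroblast genes, cell 17 held 10 and cell 40 held 9. Over 5 times the signal expected from linked cells they held 2, 5 and 3. Cells 5, 30 and 36 formed a cluster led by Myl9, Acta2, Rgs5 and Tpm2, which is pericyte- or smooth muscle-like. Cell 5 held only 3 of the 10 mural markers together with 6 myofibre genes, so the name rests on cells 30 and 36. Cells 5 and 30 also held 10 of the 12 fibro-adipogenic progenitor or fibroblast genes each, against 4 in cell 36. Only cell 36 thus held mural markers without most of the fibroblast genes. These clusters hold 3 cells each and have no replicate.

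**Figure D3:**
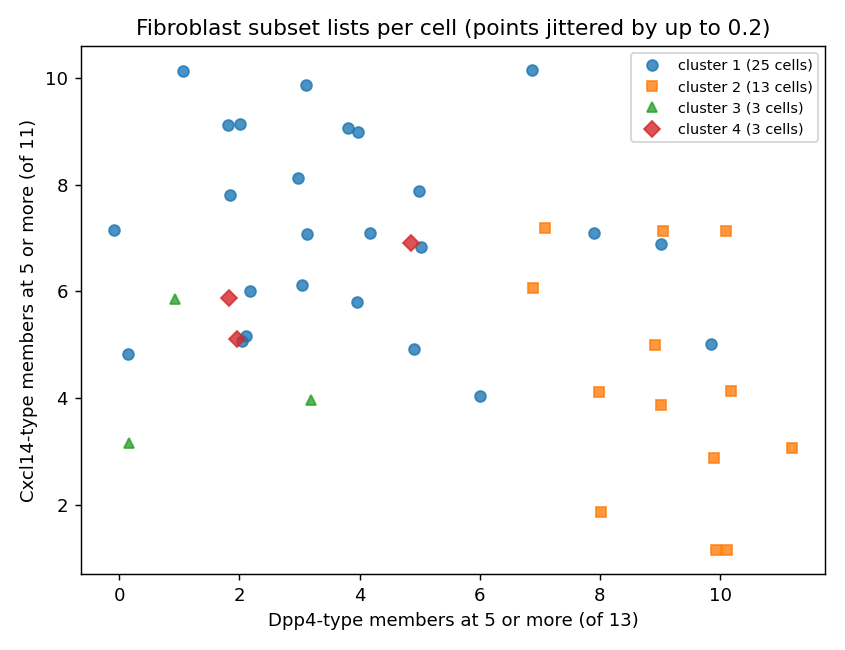
Number of Dpp4-type genes (x axis, of 13) and Cxcl14-type genes (y axis, of 11) at a log2 value of 5 or more in each of the 44 cells, with points moved sideways and upwards at random by up to 0.2 and marked by cluster. The 13 cells of cluster 2 hold 7 to 11 Dpp4-type genes, a range that some cells of cluster 1 also reach.

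Genes of lineage regulation were uneven. Among 13 adipogenic regulators Lpl was present in 35 cells at the higher threshold, Ebf1 in 26, Ebf2 in 17 and Cebpd in 15, whereas Cebpb and Pparg, the main adipocyte regulator, were present in 0. Of 7 osteochondrogenic regulators none was present in at least 22 cells at FPKM 1. Msx1 was present in 16 cells at FPKM 1, Sox5 in 10, Sox9 and Alpl in 8, Acvr1 in 6 and Runx2 in 2. Of the osteoblast list Alpl was present in 3 cells at the higher threshold, Col22a1 in 1, and Bglap, Bglap2, Spp1 and Ibsp in 0. The measured chondrocyte genes were Sox9, in 0 cells, and Col11a1, in 2.

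In the signalling lists, 14 of 25 TGF-beta and BMP genes were present in at least 22 cells at FPKM 1 and 4 at the higher threshold. Fstl1 was present in 41 cells at the higher threshold, Tgfbr2 in 34, Id3 in 28 and Tgfbr3 in 25, against 1 for Inhba and 0 for Tgfb1. Of 18 Wnt genes, 3 were present in at least 22 cells at FPKM 1 and 0 at the higher threshold, with Sfrp4 in 13 cells, Ctnnb1 in 11, Lrp6 in 9, Fzd4 in 6 and Frzb and Rspo3 in 0. Among Hedgehog genes, Boc and Gas1 were present in 10 cells each, Cdon in 9, Hhip in 2, Gli2 in 1 and Smo in 0. Of factors acting on muscle stem cells, Lama2 was present in 33 cells, Igf1 in 22, Il33 and Fgf7 in 16 each and Wisp1 and Nrg1 in 0. Of 16 complement and innate genes, 7 were present in at least 22 cells at the higher threshold and 6 in under 10% of cells. Serping1 was present in 44 cells, C1s1 in 37 and C3 and C1ra in 34 each, against 1 for Cxcl2 and 0 for Cxcl5.

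Mki67, Aurkb and Rrm2, genes of proliferating cells, were present in 0 cells at FPKM 1. At least 3 of the 16 cell cycle genes were present in 11 cells at FPKM 1 (25%, 13.2 to 40.3), in 2 cells over 5 times the signal expected from linked cells and in 0 at the higher threshold. At the last threshold Pcna was present in 12 cells, Tyms in 4, Mcm6 in 3 and Mcm5 in 2. The cell cycle inhibitor Cdkn1a was present in 32 cells, Btg2 in 17, Gas6 in 16 and Cdkn1b in 9, and Cdkn2a and Cdkn2b in 0. Of 17 immediate early and heat shock genes, 10 were present in at least 22 cells, with Hspa8 in 44 cells, Fos in 40, Zfp36 in 35 and Egr1 in 30, against 9 for Dnajb1 and 7 for Fosb. Xist was present in 44 cells at FPKM 1 and 32 at the higher threshold, and the Y-linked genes Ddx3y and Eif2s3y in 0. Uty was present in 3 cells at FPKM 1.

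The most abundant genes by median log2 value, outside ribosomal protein genes, were Fth1 at 12.70, Gpx3 at 12.63, Ftl1 at 12.25, Crip1 at 12.01, Eef1a1, Ly6a, Serping1, Igfbp6, Cst3 and Sparc at 11.46. Of the housekeeping list Eef1a1, Rplp0 and Rps27a were present in 44 cells at the higher threshold, Actb in 41 and Hprt in 5. The most variable genes were Ece1, Snora31, Apoe, Inmt, Prg4, Cxx1c, Rnu1a1, Mgp, Nsrp1 and Apod. Of these, Ece1 had quartiles of 2.82 and 9.38 and Apoe of 4.23 and 11.22. Ece1 was the leading gene of a planned cluster made up of 1 whole block of linked libraries, with a mean log2 value of 10.5 against 5.58. It reached the higher threshold in 7 of its 7 cells and 18 of the other 37. Nsrp1 was among the leading genes of another whole block, in 4 of 7 cells and 7 of the other 37. Leading genes were picked by their difference between clusters, so these values restate that choice. A mean of 10.5 also lies far above the low values that linked libraries share. Of list genes, Sfrp4, Acta2, Tagln and Uchl1 were also among the leading genes of planned clusters. Uchl1, of the Dpp4-type list, reached the higher threshold in 6 of the 10 cells of a planned cluster that holds a whole block and in 3 of the other 34. Only 4 of the 10 most variable genes were shared under a pseudocount of 0.1.

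**Figure D4:**
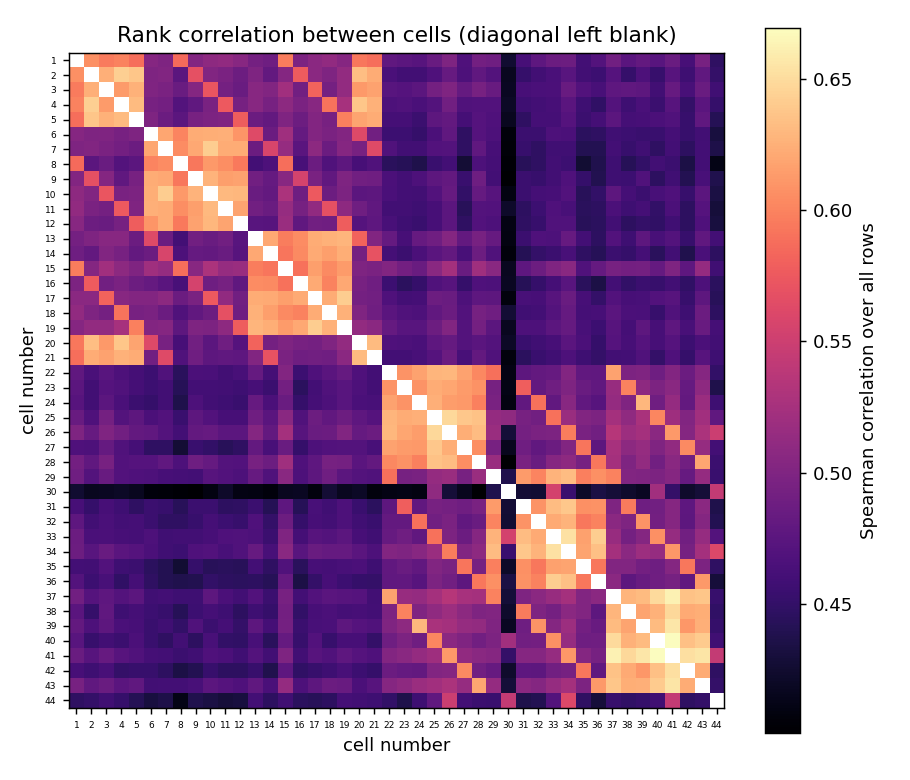
Spearman correlation over all rows between each pair of the 44 cells (colour), in order of cell number on both axes, with the diagonal blank. Blocks of 7 cells and stripes of cells mostly a multiple of 7 apart have medians of 0.622 and 0.589, against 0.495 for unlinked pairs of the same set. Linked pairs were picked by their correlation over every other row, so the higher medians were in part set by that choice.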

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

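The threshold of a log2 value of 5, the one over 5 times the signal expected from linked cells, leaving out the 2 cells in no block or 1 block, and all settings of the clustering with values under 5 set to 5 were chosen after seeing the data. At FPKM above 0, FPKM 0.1, 5 and 10 and the log2 value of 5, the median number of genes per cell was 6722, 6630, 2498, 2094 and 1540. The normalization fixes this number at FPKM 1 and above. In the same order Prrx1 was present in 44, 44, 31, 29 and 23 cells, and in 32 over the signal expected from linked cells. Prrx1 and Pdgfra were found together in 44, 44, 27, 24 and 17 cells, and in 23 over that signal. Cells with at least 3 markers of another lineage numbered 44, 44, 28, 20 and 13, and 24 over that signal, and the count was 44 with 2 markers and 26 with 5. List genes in at least 22 cells numbered 153 of 329 at FPKM 1, 92 at FPKM 10, 79 at a log2 value of 5 and 96 over the signal expected from linked cells. All 44 cells passed each cell filter, so those alternatives moved nothing and show no stability. Leaving out the 2 cells in no block moved none of these 4 counts beyond the interval or ratio used.

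Agreement of the planned clusters with themselves under other settings, as the adjusted Rand index, was 0.748 with list genes included, 0.316 with average linkage on Spearman correlation, 0.779 with TPM, 0.507 with 5 principal components and 0.0416 with values under 5 set to 5. The cells already had nearly equal sums, from 579623 to 579912, so TPM multiplied all cells by nearly the same factor. It therefore corrects no difference between cells. The clustering with values under 5 set to 5 moved with most of its settings. The index was 0.474 with 500 genes, 0.7625 with 2000, 0.7875 with list genes included, 0.550 with k-means, 0.690 and 0.614 with floors of 4 and 6. It was 0.675 with the first row kept for repeated symbols, the form in which this clustering was first run. That form replaced 2 of the 1000 genes and gave 5 clusters, with 10 cells in place of 13 in the cluster with the most Dpp4-type genes. Other causes of these changes were not tested. Over single genes and lists, 178 values moved and 321 did not, and at the log2 value of 5 alone 36 moved and 35 did not. With TPM 7 moved and 64 did not, but TPM acts here only as a lower threshold. Of the main value of each comparison, 40 alternatives moved and 41 did not, the latter including the cell filters that remove no cell. Sequencing depth is unknown, so absence of a gene was not detectable apart from low depth.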

Other observations

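All tests in this part were chosen after the results they bear on had been seen. The cluster of 13 cells was compared with the other 31 in further lists at a log2 value of 5 or more (members per cell, SD over cells). Cell cycle inhibitors and quiescence genes numbered 1 ± 0.707 of 11 against 2.42 ± 1.26. The gap was widest for Btg2, present in 0 of the 13 cells and 17 of the other 31, while Rb1, in 2 and 2, went the other way. Hedgehog genes numbered 0.308 ± 0.480 of 9 against 1.03 ± 0.836. Collagens were close, at 7.77 ± 1.54 of 16 against 8.19 ± 1.54.

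Low values were shared within blocks of 7 cells and along stripes between blocks. For 377 genes strong in 1 cell only, in rows not used to find the links, the share above the lowest value was 60.7 percentage points higher in linked cells, at 0.278% of the source level at the median. True low expression in all cells is argued against, since unlinked cells of the same set showed 19.7% against 80.4%. A shared animal or day for each block alone is argued against by the stripes, since 66.7% of linked pairs in different blocks were a multiple of 7 apart in cell number, against 14.3% of all such pairs. Signal carried between libraries that share an index may therefore account for the pattern, but the index of each library is not given in the sources used here.

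The planned clusters followed these blocks, with an adjusted Rand index of 0.815. With values under 5 set to 5 the index fell to 0.0267. Low-level carried signal may thus have set the planned clusters. In the simulation a carry-over of 0.3% did not, since 100% of cells were placed correctly, but the simulated groups differed strongly. A real difference between blocks was not tested and stays open.

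The cluster of 13 cells was high in Dpp4-type and low in Cxcl14-type genes. The blocks of linked cells do not hold it alone: 12 of its 13 cells lie in blocks, in 6 of the 6, and cell 44 in none. Within each block they held 4 to 6 more Dpp4-type genes than the others, but 5 of them are in block 4 (cells 22 to 28), 4 blocks have only 1 each, and the Cxcl14-type difference was negative in 4 of 6 blocks (-2.67 without block 4, against -2.62). Without block 4 the Dpp4-type difference was 5.71, against 5.56. Cells 24 to 28, 35 and 44 of the cluster of 13 also stand together in the planned cluster that holds block 4. Uchl1, a Dpp4-type gene also among the leading genes of the planned cluster that holds block 4, was present at a log2 value of 5 or more in 8 of the 13 cells and 1 of the other 31. Whether fewer genes were measured in its cells cannot be told apart from the values, since the normalization fixes the number of genes at FPKM 1 and the median number above the lowest value, 175 higher with an SD over all cells of 494, rests on low values shared between linked libraries. Whether other gene lists part these cells as much also stays open. Among 10000 random lists matched on mean level, the Dpp4-type difference lay at percentile 100 (5th to 95th percentile -0.844 to 1.17) and the Cxcl14-type difference at percentile 0 (-0.740 to 1.01), but such lists hold unrelated genes, which spread less than a co-regulated list would. The cluster was picked by its Dpp4-type genes, so that difference, +42.8% of the list and more than in any of 29 other lists, was in part set by the choice. The Cxcl14-type difference was -23.8% of the list, and 1 of the 29 other lists, immediate early and heat shock genes, parted the cells as much, at -26.5%. The number of cells ranged from 10 to 15 over settings, and some cells outside the cluster also hold many Dpp4-type genes. An unequal response to digestion or a difference between animals was not tested and stays open beside a difference between fibroblast states, and cells from named animals would be needed to part them.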
